A study of Homo sapiens with 30 samples.

How the data were processed

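RNA-seq was performed on H1 human embryonic stem cells in 3 groups of 2 libraries, WT, DNMT3B knockout (KO) and DNMT3B PWWP deletion (dPWWP), as given by the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and a column after DNase treatment, and libraries were made with the ScriptSeq v2 kit and selected by size on a gel. The series holds 30 samples, and the 24 that are not RNA libraries (bisulfite and chromatin samples) were not used here; the labels of 1 chromatin sample conflict and it was assigned to no group. The authors deposited FPKM values (fragments scaled by transcript length and by the library's total), as 1 file per library and 1 table with a value per group. Per the submitters' processing notes, the tools of the whole series include STAR, Cufflinks and Cuffdiff and the builds GRCh38 and hg38, with no role or version; the annotation, the use of strand and the scaling between libraries are not given in the sources used here. Each library file lists 58206 rows for 58161 gene IDs. In the deposited group table, 65 genes differ by more than 0.1% from the mean of the 2 library values, and 20 features with such a gene were among those kept. The FPKM sums of the libraries run from 490875 to 709718 and low values have no common step, so reads could not be recovered, depth is unknown, and no confidence interval from counts is given.

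Gene IDs were matched to symbols through the supplied name table (57379 of 58161 IDs, 41792 with a symbol), and positions came from the RefSeq annotation of GRCh38. IDs sharing a symbol were summed, and Y-linked genes and XIST were left out, leaving 56552 features. A feature was kept if FPKM was at least 1 in at least 2 of the 6 libraries, which left 17181, of which 12833 were protein-coding and 2106 carried only clone-based names or IDs. One linear model with the 3 groups was fitted by limma 3.58.1 in R 4.3.3 to log2(FPKM + 1), with 3 residual degrees of freedom, a mean-variance trend and two-sided tests, and p-values were adjusted by Benjamini-Hochberg over all kept features. Adjusted p-values in the text come from limma unless camera or fry is named, a fold change is on the log2(FPKM + 1) scale, which understates changes of low genes, and features were called at an adjusted p under 0.05. The exact level of 0 in a file without counts can be a failed estimate, so features at 0 in both libraries of a group are described as listed at 0.

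Before the data were examined, 26 gene lists were fixed, covering DNA methylation, pluripotency, germ layers, germline, imprinting, chromatin, stress, cell cycle and other groups. HOX clusters had 0 members kept and X-linked cancer-testis families 4, so the 24 lists with at least 5 kept members were tested with camera (preset correlation of 0.01, adjusted over the 24 lists of each comparison), again with an estimated correlation, and with fry, whose one-directional p does not compare a list with other genes. With an estimated correlation 0 lists passed in any comparison (lowest adjusted p 0.827, 0.835 and 0.718 for KO vs WT, dPWWP vs WT and KO vs dPWWP). That form rests on 3 residual degrees of freedom and was not run on simulated data. Its power is unknown and may be very low, so not passing it does not by itself argue against a list. By fry, 3, 0 and 0 lists passed. Genes named in the text follow a rule fixed before the data were examined: DNMT3B, the 10 largest changes per direction among called genes whose libraries did not overlap between the groups and whose mean was at least 3 FPKM in the higher group, leaving out clone-based, microRNA and small RNA names, and up to 4 members per list with the smallest adjusted p. Repeating the 10 largest changes over protein-coding genes, and choosing which of the genes so found to describe, was done after the values were seen. One gene found by the rule is not reported here.

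Scripts were tested on simulated data with the real means and 17181 features. At a simulated log2 change of 0.5, 0% of changed genes were recovered in KO vs WT, 1.49% in dPWWP vs WT and 1.49% in KO vs dPWWP. At a change of 1 the shares were 31.3%, 37.3% and 34.3%, and at 2 they were 89.4%, 81.8% and 87.9%. Unchanged genes made up 5 of 85, 13 of 93 and 9 of 91 calls in the 3 comparisons. Each simulation changed 67, 67 and 66 genes at the 3 sizes, far fewer than were called against WT. The shares need not carry over to those comparisons. A list shifted by 0.5 passed camera with the preset correlation in each comparison, with 0 other lists. Simulated genes were drawn independently of each other, so this does not show how often lists pass when genes vary together. For the overlap of comparisons that share WT, 100 simulations drew unchanged groups. Sets of genes were compared with 10000 random sets of like expression. Alternatives covered the pseudocount, filter, 4 other scalings, the fit, the replicate number as a block, each library left out and the list tests. Restricting the test to protein-coding genes, and leaving out the features that differ between the deposited tables, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.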

Results

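RNA was sequenced from H1 cells, an established human embryonic stem cell line, in 3 groups of 2 libraries. The groups were unedited cells (WT), cells in which DNMT3B had been knocked out with CRISPR-Cas9 (KO), and cells in which the PWWP domain of DNMT3B had been deleted (dPWWP). DNMT3B is a de novo DNA methyltransferase, and its PWWP domain binds histone H3 methylated at lysine 36. The series title places the comparisons in the context of DNA methylation and bivalent promoters, so the questions addressed here are which transcripts differ when DNMT3B is knocked out or its PWWP domain is deleted, and whether the 2 edited lines differ from each other. Methylation and chromatin samples of the series were not used here. The measurement was FPKM per gene, and the sequencing depth of each library is unknown. WT libraries listed 23654 and 20971 features above 0, KO libraries 27528 and 28224, and dPWWP libraries 27987 and 27522. Small RNA genes held 25.74% of the summed FPKM in WT replicate 2, against 9.01% in WT replicate 1, 9.87% and 13.45% in KO, and 8.51% and 10.08% in dPWWP. Across kept genes, the correlation of log2 values was 0.9354 between the WT libraries, 0.9718 between the KO libraries, 0.9691 between the dPWWP libraries, and between 0.89 and 0.9127 for a WT library against an edited one. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The fit shared its spread over the 3 groups, while the WT libraries correlated least, so adjusted p-values against WT may be too small.

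DNMT3B transcript was lower in KO cells and remained detected in every library. DNMT3B (ENSG00000088305, GRCh38 chromosome 20, 32762385 to 32809356) measured 341 ± 20.6 FPKM in WT, 161 ± 20.9 in KO and 250 ± 6.24 in dPWWP cells (SD, n = 2 each). In KO against WT the log2 fold change was -1.08 ± 0.15 (SE), with an adjusted p of 0.0117 by limma. In dPWWP against WT it was -0.44 (adjusted p = 0.0897), and KO against dPWWP gave -0.63 (adjusted p = 0.304), so neither of these differences passed the test. With libraries rescaled to a fixed total, the dPWWP change against WT was -0.17 (limma adjusted p = 0.636), and under quantile normalization it was -0.23 (adjusted p = 0.478). Where the edits lie in the gene is not given in the sources used here, and a gene-level FPKM does not tell edited from intact transcript. The KO call was lost when libraries were rescaled to a fixed total (TPM; -0.86, adjusted p = 0.0541), without KO replicate 1 (-0.95, adjusted p = 0.0756) and without KO replicate 2 (-1.21, adjusted p = 0.0745), and the adjusted p ranged from 0.00272 to 0.0756 over all alternatives.

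**Figure D1:**
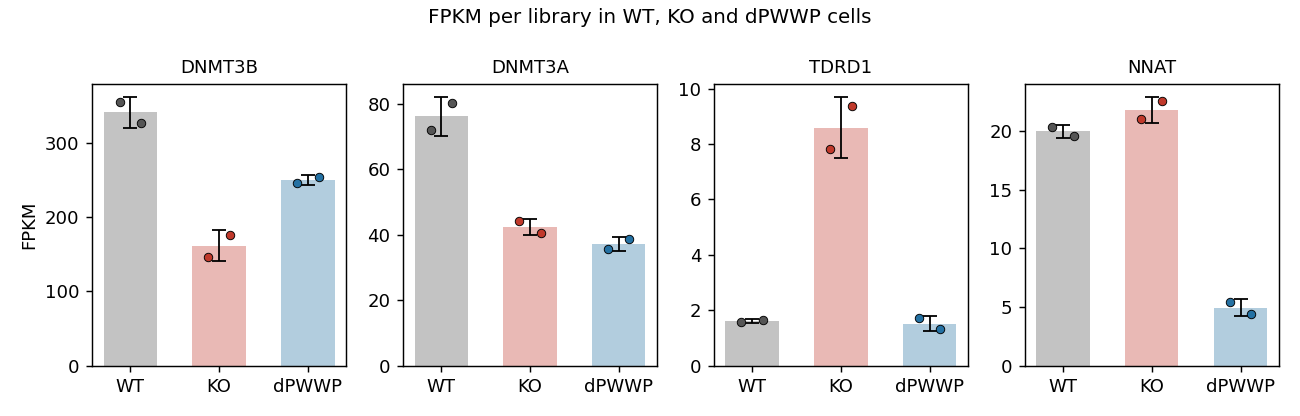
FPKM of DNMT3B, DNMT3A, TDRD1 and NNAT in WT, KO and dPWWP cells; points are libraries, bars are group means and error bars are SD (n = 2 per group). Mean DNMT3B was 341 in WT, 161 in KO and 250 in dPWWP cells, TDRD1 was higher in both KO libraries than in the other 4, and NNAT was lower in both dPWWP libraries than in the other 4.

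In KO cells, ARMCX1, encoding an armadillo repeat protein of mitochondria, rose from 1.91 and 2.04 FPKM in the WT libraries to 22.2 and 19.2, and BSCL2, encoding the lipid droplet protein seipin, rose from 1.82 and 2.65 to 16.1 and 22.1. STMN2, a neuronal microtubule regulator, and CTSK, a lysosomal protease, rose as well. EEF1A2, a tissue-restricted translation elongation factor, fell from 18.8 and 19.7 FPKM to 2.56 and 2.79, and SRRM2, a splicing factor of nuclear speckles, fell from 106 and 101 to 21.4 and 22.1. The immediate early transcription factors EGR1 and FOS, the histone methyltransferases KMT2A, KMT2C, KMT2D and KMT2E, and 9 of 15 transcripts of the mitochondrial genome fell as well. Of 17181 features tested, 1474 were higher and 1816 lower in KO than in WT cells (limma, adjusted p under 0.05), among them 994 higher and 1164 lower protein-coding genes.

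Among the largest changes, the log2 fold change was 2.86 ± 0.20 for ARMCX1 (SE, adjusted p = 0.00309), 2.63 ± 0.21 for BSCL2 (adjusted p = 0.00385), -2.46 ± 0.13 for EEF1A2 (adjusted p = 0.00116) and -2.20 ± 0.12 for SRRM2 (adjusted p = 0.00127). PKIB, an inhibitor of protein kinase A, rose by 2.43, STMN2 by 2.30 and CTSK by 2.29. GPAT2, an acyltransferase known from testis, rose from 0.33 and 0 FPKM to 4.22 and 5.84. TRPM2, a calcium-permeable channel, was listed at 0 in both WT libraries and measured 3.89 and 4.91 FPKM in KO. On the other side, EGR1 changed by -2.83, ZDHHC11, a palmitoyltransferase, by -2.46, FOS by -2.33, and CPT1B, which carries fatty acids into mitochondria, by -2.33. Some non-coding features differed between WT and KO cells as well. VTRNA2-1, a vault RNA-like transcript, was listed at 0 in both WT libraries and at 210 and 130 FPKM in KO. Of 26 kept intronic transcripts, 14 were called lower and 0 higher in KO against WT by limma, and 11 and 0 in dPWWP against WT. Among them, NALF1-IT1 measured 15.0 and 14.2 FPKM in WT and 0.51 and 0.88 in KO, and THBS1-IT1 11.6 and 8.52 in WT and 0.58 and 0.22 in KO. The pseudogene RPL41P1 was listed at 0 in all WT and dPWWP libraries and at 134 and 188 FPKM in KO, but pseudogenes and small RNAs can share reads with near-identical copies, so these values are uncertain.

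Of 24 germline genes kept, 9 rose in KO cells and 0 fell by limma (12 rose when adjusted over the list alone), and the list passed camera with an adjusted p of 0.0286 but had an adjusted p of 0.827 with an estimated correlation. TDRD1, a Tudor protein of the piRNA pathway, rose by 1.87 ± 0.19 on the log2 scale, PIWIL2, a piRNA-binding Argonaute protein, by 1.12, DMRTB1 by 1.35 and PABPC3 by 1.02. The list call was lost by fry (adjusted p = 0.0531), at a pseudocount of 0.1 (0.0557), with a filter on a mean FPKM of at least 1 (0.119) or on at least 5 FPKM in 2 libraries (0.142), under TPM scaling (0.0608) and after rescaling without mitochondrially encoded and small RNA genes (0.0762). It was also lost without WT replicate 1 (0.239), without KO replicate 1 (0.0541) and without KO replicate 2 (0.128), and its adjusted p ranged from 0.0126 to 0.827 over all alternatives. Of 28 enzymes of H3K36 and H3K4 methylation, 16 fell and 0 rose (camera adjusted p = 8.41e-06, adjusted p = 0.827 with an estimated correlation). KMT2D fell by 1.91, KMT2E by 1.48, KMT2A by 1.34 and KMT2C by 1.23 on the log2 scale. Of 15 mitochondrially encoded genes, 9 fell and 0 rose (camera adjusted p = 2.39e-05, adjusted p = 0.827 with an estimated correlation), with MT-RNR2 at -2.62, MT-ND2 at -1.42 and MT-ND1 at -0.87. These medians, 0.69 for germline genes, -0.50 for the methylation enzymes and -0.70 for the mitochondrial genes, kept their sign under each of the 4 other scalings, but the counts did not hold under TPM, where 6 germline genes rose, 2 methylation enzymes fell (median -0.28) and 5 mitochondrial genes fell. The mitochondrial and methylation enzyme changes followed the same division of libraries as the number of features above 0 and the intronic transcripts.

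Of 36 clustered protocadherins, cell adhesion genes of neural development, 9 fell and 3 rose in KO cells (camera adjusted p = 0.0286, adjusted p = 0.944 with an estimated correlation). The 9 that fell belong to the gamma cluster, with PCDHGB2 at -1.64 and PCDHGB7 at -1.18, while PCDHB5 rose by 1.27 and PCDHA1 by 1.20; members of the alpha and gamma clusters share their last exons, so reads of single members are uncertain. The protocadherin call was lost with a filter of at least 5 FPKM in 2 libraries (adjusted p = 0.56), by fry (0.17) and without WT replicate 1 (0.36). Among 23 DNA methylation writers, readers and erasers, 7 fell and 3 rose. HELLS, a chromatin remodeller needed for DNA methylation, fell by 1.75, the dioxygenase TET1 by 0.85 and the methyltransferase DNMT3A by 0.83, from 72.0 and 80.4 FPKM to 44.1 and 40.5. Only 32 of the 200 bivalent developmental transcription factors on the list were kept; SP8 rose by 1.26, BCL11B changed by -1.35 and BNC1 by -0.82, and the other 29 did not pass. Of 32 core pluripotency genes, 3 rose and 5 fell, with GDF3 at 1.33, ZIC2 at -0.80 and ESRG at -0.66, and of 11 naive pluripotency genes 2 rose, including DPPA3 at 1.28. Among 29 imprinted genes, 5 rose and 7 fell, with NDN at 1.22, INPP5F at 0.97, ZDBF2 at -0.83 and ZNF331 at -0.62. None of these 5 lists passed camera, with an adjusted p of 0.54 for DNA methylation, 0.909 for bivalent factors, 0.425 for core and 0.131 for naive pluripotency, and 0.991 for imprinted genes, while the DNA methylation list passed fry downward (adjusted p = 0.0393). Under TPM the members that rose and fell were 2 and 1 for protocadherins, 0 and 1 for DNA methylation, 1 and 1 for bivalent factors, 2 and 0 for core pluripotency and 4 and 0 for imprinted genes. The medians of DNA methylation and core pluripotency genes turned from -0.10 and -0.20 to 0.10 and 0.01 under TPM. The median of all features also moved up by 0.2027 under TPM, so the turned signs do not show a change relative to other genes.

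The split of the KO calls depended on scaling. As deposited, 44.8% of the calls were higher in KO, against 70% under TPM scaling (921 higher, 394 lower) and 59.4% after rescaling without mitochondrially encoded and small RNA genes (1655 higher, 1133 lower); these scalings moved the median of all genes by 0.2027 and 0.1079 on the log2 scale. With 1 KO library left out the counts were far lower, 101 higher and 119 lower without KO replicate 1 and 42 higher and 21 lower without KO replicate 2. Of the genes named for KO against WT, 38 lost their call without KO replicate 1 and 48 without KO replicate 2, TDRD1 and PIWIL2 among them in both cases, whereas ARMCX1, BSCL2, EEF1A2 and SRRM2 passed without either library.

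In dPWWP cells, ZNF300, a KRAB zinc finger gene, rose from 0.69 and 0.71 FPKM in the WT libraries to 14.9 and 20.2, and ARRB1, encoding a beta-arrestin, rose from 5.35 and 5.29 to 45.0 and 41.3. ADCY8, an adenylate cyclase, rose from 4.12 and 3.55 to 20.2 and 20.7. LIPN, a lipase gene, was listed at 0 in all WT and KO libraries and at 7.81 and 8.42 FPKM in dPWWP. CHCHD2, encoding a mitochondrial intermembrane space protein, was listed at 0 in both dPWWP libraries and at 26.1 and 28.7 FPKM in WT, and CEBPZOS fell from 55.1 and 61.7 to 8.23 and 4.10. Of 17181 features, 1369 were higher and 1552 lower in dPWWP than in WT cells by limma, among them 951 higher and 948 lower protein-coding genes.

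The log2 fold change against WT was 3.44 ± 0.20 for ZNF300 (SE, adjusted p = 0.00207), 2.80 ± 0.17 for ARRB1 (adjusted p = 0.00226), 2.15 ± 0.17 for ADCY8 (adjusted p = 0.00417) and -3.11 ± 0.28 for CEBPZOS (adjusted p = 0.0058). ARMCX1 rose by 2.66, BSCL2 by 2.44 and OR52A1, an olfactory receptor gene, by 2.53. SRRM2 changed by -2.08, EGR1 by -2.35, ZDHHC11 by -2.35, COL1A1, a fibrillar collagen gene, by -2.08 and the matrix protein gene CCN1 by -1.42. ZNF630, another zinc finger gene, measured 2.89 and 3.03 FPKM in WT and was listed at 0 in both dPWWP libraries, and ZNF680 changed by -1.97. BAX, an apoptosis effector, rose by 1.56 in dPWWP and by 1.52 in KO cells.

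Of 28 enzymes of H3K36 and H3K4 methylation, 11 fell and 0 rose in dPWWP cells (camera adjusted p = 7.67e-05, adjusted p = 0.835 with an estimated correlation), with KMT2D at -1.73, KMT2A at -1.17, ASH1L at -0.81 and NSD3 at -0.78. Of 15 mitochondrially encoded genes, 7 fell and 0 rose (camera adjusted p = 1.07e-05, adjusted p = 0.835 with an estimated correlation), with MT-RNR2 at -2.27 and MT-ND2 at -1.32. Under TPM, 1 methylation enzyme fell and the list median was -0.08 instead of -0.35, and 3 mitochondrial genes fell. Of 49 replication-dependent histone genes, 6 fell and 0 rose (camera adjusted p = 0.00329, adjusted p = 0.835 with an estimated correlation), with H2AC14 at -1.91, H2AC25 at -1.44 and H2AC16 at -1.26. H2AC14 measured 941 and 1801 FPKM in WT replicates 1 and 2, and the histone call was lost under quantile normalization (adjusted p = 0.25), without WT replicate 2 (0.224) and without dPWWP replicate 2 (0.101). The 77 cytosolic ribosomal protein genes passed camera downward (adjusted p = 0.0384, adjusted p = 0.835 with an estimated correlation), but 0 members passed limma over all genes; RPL26 had -1.06 (adjusted p = 0.0708) and RPLP2 -0.62 (adjusted p = 0.0548). At an unadjusted p under 0.05, 6123 of the 17181 features differed. The ribosomal list median was -0.25 as deposited, 0.03 under TPM, which moved the median of all features up by 0.2569, and 0.20 under quantile normalization. Under quantile normalization the list passed camera upward (adjusted p = 0.00081). The downward call was lost under TPM (camera adjusted p = 0.133) and in a fit on the 2 groups alone (0.0693). It was also lost without WT replicate 2 (0.887), KO replicate 1 (0.068), KO replicate 2 (0.0724), dPWWP replicate 1 (0.173) or dPWWP replicate 2 (0.135). By fry, 0 lists passed in dPWWP against WT.

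Of 24 germline genes, 0 rose and 1 fell in dPWWP cells, ZCWPW1, a histone reader of meiosis, at -1.24; MEIOB, a meiotic gene, had 1.15 (adjusted p = 0.0527). Among 23 DNA methylation genes 5 fell, with HELLS at -1.41, DNMT3A at -1.02 and TET1 at -0.69. Of 32 bivalent transcription factors SP8 alone passed, at 0.59, and BNC1 had -0.77 (adjusted p = 0.0595). Of 36 protocadherins 8 fell and 1 rose, with PCDHGA4 at -1.40 and PCDHB5 at 1.37. Imprinted genes split into 3 that rose and 7 that fell of 29. NNAT, a paternally expressed gene inside an intron of BLCAP, fell by 1.83 from 20.4 and 19.6 FPKM to 5.46 and 4.42, L3MBTL1 fell by 1.48, NDN rose by 1.30 and CDKN1C by 1.06. Core pluripotency genes split evenly, 4 rising and 4 falling of 32, with LEFTY1 at 1.51, FGF4 at 0.62, ESRG at -0.78 and ZIC2 at -0.89. These lists did not pass camera (adjusted p between 0.0988 for protocadherins and 0.709). Under TPM the members that rose and fell were 1 and 0 for germline genes, 0 and 1 for DNA methylation, 0 and 0 for bivalent factors, 1 and 1 for protocadherins, 4 and 1 for imprinted genes and 1 and 0 for core pluripotency. The medians of germline, DNA methylation and core pluripotency genes turned from -0.08, -0.09 and -0.18 to 0.14, 0.18 and 0.08 under TPM. TPM also moved the median of all features up by 0.2569 in this comparison, so the turned signs do not show a change relative to other genes.

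As deposited, 46.9% of the dPWWP calls were higher, against 76.6% under TPM scaling (1063 higher, 325 lower) and 65.3% after rescaling without mitochondrially encoded and small RNA genes (1676 higher, 892 lower), which moved the median of all genes by 0.2569 and 0.1269. The counts were 57 higher and 23 lower without dPWWP replicate 1, 96 and 78 without dPWWP replicate 2, 544 and 609 without KO replicate 1, and 603 and 660 without KO replicate 2. Of the genes named for dPWWP against WT, 37 lost their call without dPWWP replicate 1, ADCY8 among them, and 31 without dPWWP replicate 2, whereas ZNF300, ARRB1, CEBPZOS, ARMCX1 and SRRM2 passed without either library.

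KO and dPWWP cells differed in far fewer transcripts, 37 higher and 21 lower in KO by limma (15 and 8 protein-coding). CEBPZOS was higher in KO, at 73.9 and 61.8 FPKM against 8.23 and 4.10 in dPWWP, and NNAT at 21.8 ± 1.11 against 4.94 ± 0.738 (SD, n = 2). The piRNA pathway gene TDRD1 was higher in KO, at 7.80 and 9.37 FPKM against 1.71 and 1.32, as was GPAT2, at 4.22 and 5.84 against 0.19 and 0.08. EEF1A2, ARRB1, ADCY8 and ZNF300 were lower in KO than in dPWWP. CHCHD2 measured 39.6 and 51.9 FPKM in KO and was listed at 0 in both dPWWP libraries.

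The log2 difference between KO and dPWWP was 3.32 ± 0.28 for CEBPZOS (SE, adjusted p = 0.0122), 1.95 ± 0.14 for NNAT (adjusted p = 0.00617), 1.93 ± 0.19 for TDRD1 (adjusted p = 0.0223), -2.94 ± 0.20 for ZNF300 (adjusted p = 0.00569), -1.89 ± 0.17 for ARRB1 (adjusted p = 0.0175) and -1.88 ± 0.13 for EEF1A2 (adjusted p = 0.00569). VAV1, a guanine nucleotide exchange factor of blood cells, differed by 2.18, TRPM2 by 2.17, MOK, a protein kinase, by 1.96, C5orf63 by 1.90 and LRRC61 by 2.44. ZBED10P, which lies within LRRC61, differed by 2.44, so reads of these overlapping genes cannot be told apart. GNAS-AS1, antisense to the imprinted gene GNAS, differed by 2.52 and IDI2-AS1 by 2.39, while GNAS itself had -0.50 (adjusted p = 0.254); whether the counting used strand is not given in the sources used here. Lower in KO were GAMT, an enzyme of creatine synthesis, at -1.95 (1.31 FPKM on average in KO and 7.90 in dPWWP), ADCY8 at -1.79, RASA3 at -1.78, CPS1, an enzyme of the urea cycle, at -1.56, and the pseudogene HMGA1P3 at -2.35. LIPN was listed at 0 in both KO libraries. Of the 58 features called, 28 were listed at 0 in both libraries of 1 of the compared groups, 3 of them protein-coding; the remaining calls were 20 higher and 10 lower in KO.

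**Figure D2:**
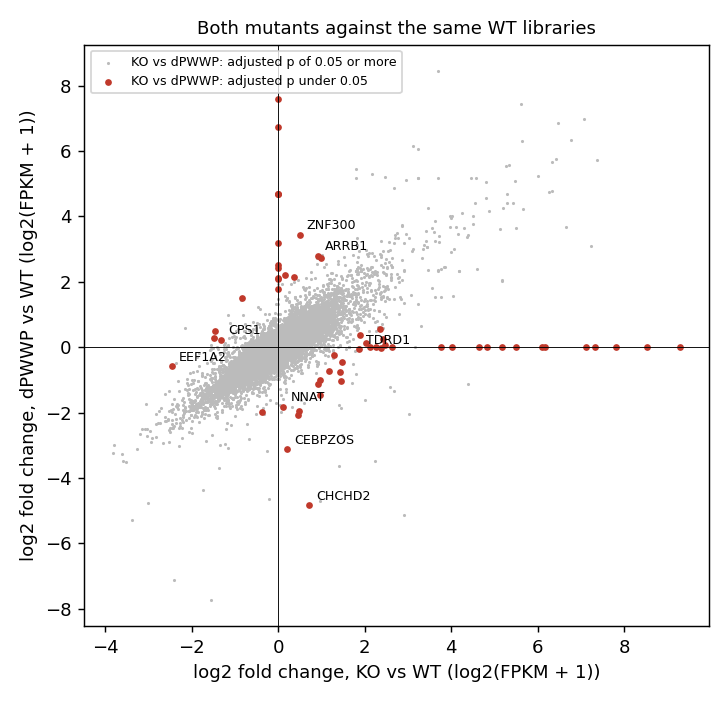
Log2 fold change of each of 17181 features on the log2(FPKM + 1) scale, KO against WT on the horizontal axis and dPWWP against WT on the vertical axis; red points are the 58 features that passed limma between KO and dPWWP. CHCHD2, CEBPZOS and NNAT lie below the diagonal and ZNF300 and ARRB1 above it, and red points lying on an axis line are mostly features listed at 0 in 4 of the 6 libraries.

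Of 24 germline genes, 21 had a positive log2 difference between KO and dPWWP, with a median of 0.52, and the list passed camera (adjusted p = 2.64e-09, adjusted p = 0.718 with an estimated correlation). TDRD1 alone passed over all genes, against 7 adjusted over the list alone; HENMT1, a piRNA methyltransferase, had 0.97 (adjusted p = 0.118), PIWIL2 0.87 (adjusted p = 0.176) and PRAME 1.07 (adjusted p = 0.219). Replication-dependent histone genes had a positive difference in 47 of 49 members, with a median of 0.44 and a camera adjusted p of 6.79e-15 (adjusted p = 0.964 with an estimated correlation), though 0 members passed limma over all genes. H3C1 had 1.40 (adjusted p = 0.105), H4C1 1.17 (adjusted p = 0.334) and H2BC12 0.72 (adjusted p = 0.317). Cytosolic ribosomal protein genes had a median of 0.12 (camera adjusted p = 0.00657, adjusted p = 0.964 with an estimated correlation), also with 0 members past limma; RPLP1 had 0.30 (adjusted p = 0.634) and RPL39 0.43 (adjusted p = 0.651). The ribosomal difference had a median of -0.02 under quantile normalization (adjusted p = 0.904) and was lost without KO replicate 1 (0.144), without dPWWP replicate 1 (0.0548) and without dPWWP replicate 2 (0.119). At an unadjusted p under 0.05, 1477 of the 17181 features differed. By fry, 0 lists passed in this comparison. Among bivalent transcription factors, BCL11B had -1.13 (adjusted p = 0.152) and OLIG3 1.18 (adjusted p = 0.207), and 0 of 32 passed. Among DNA methylation genes, UHRF1 had 1.21 (adjusted p = 0.131) and GADD45B -1.49 (adjusted p = 0.0811), and 0 of 23 passed.

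The KO against dPWWP counts fell to 1 higher and 6 lower without KO replicate 1, 1 and 8 without KO replicate 2, 20 and 2 without dPWWP replicate 1, and 20 and 0 without dPWWP replicate 2, where the lone library was assumed to vary like the other groups. TDRD1 lost its call without each of the 4 KO and dPWWP libraries in turn, CEBPZOS without either KO library, and NNAT without either KO library or dPWWP replicate 2, while CHCHD2 passed in each of these fits. Restricting the test to protein-coding genes, an alternative chosen after the data were seen, gave 60 higher and 42 lower.

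**Figure D3:**
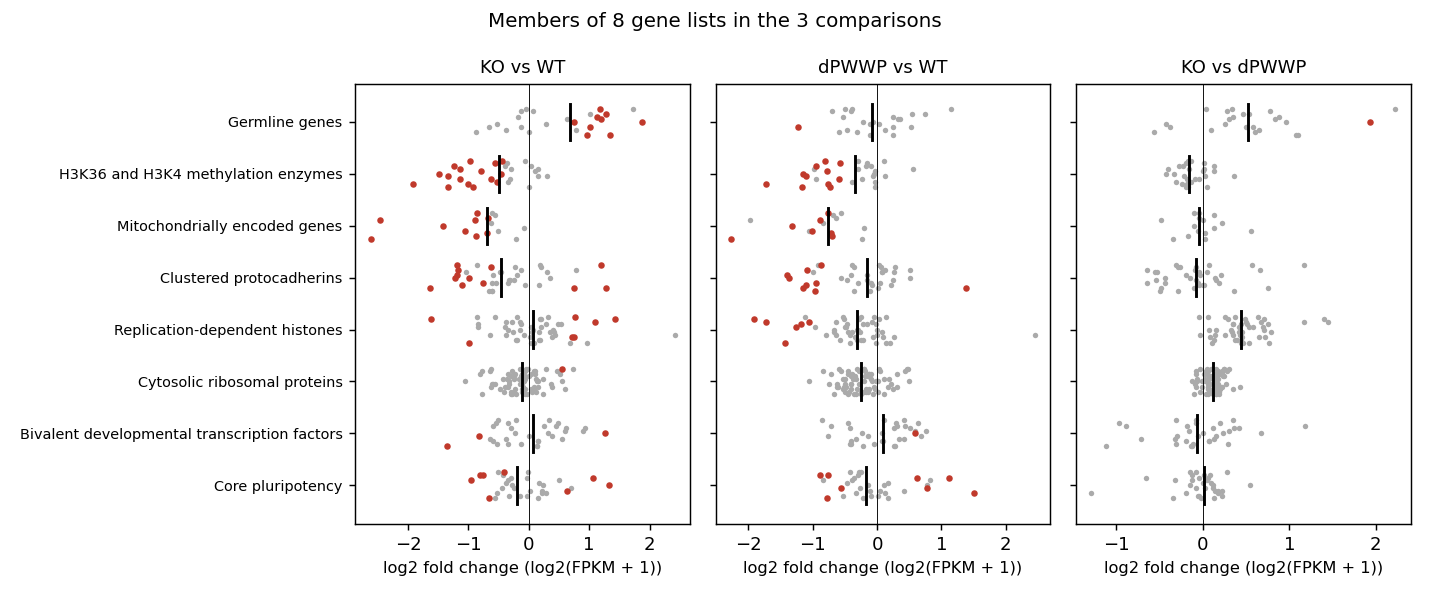
Log2 fold change on the log2(FPKM + 1) scale (horizontal axis) of the kept members of 8 gene lists in each of the 3 comparisons; each point is a gene, red points passed limma over all genes and black lines are list medians. Germline genes had a median of 0.69 in KO against WT and -0.08 in dPWWP against WT, H3K36 and H3K4 methylation enzymes -0.50 and -0.35, and cytosolic ribosomal proteins -0.11 and -0.25. The ribosomal medians turn positive under TPM and quantile scaling, and the germline median in dPWWP under TPM. TPM moved the median of all features up by 0.2027 in KO and 0.2569 in dPWWP against WT.

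Calls against WT overlapped between the 2 edited lines. Among features called in both comparisons, 912 were higher in both, 1207 lower in both and 6 opposite. ARMCX1, BSCL2, BAX, NDN, TUBB3, PCDHB5 and IFITM3 rose in both edited lines, and SRRM2, ZDHHC11, COL1A1, CCN1, KMT2D, KMT2A, DNMT3A, TET1, HELLS, MT-RNR2 and BST2 fell in both. The same WT libraries served both comparisons, and independent lists of these sizes would share 117.4 and 164. Simulations that redrew all 6 libraries without any change gave a mean of 0.04 shared higher and 0.03 shared lower calls. Unchanged groups yield almost no calls, so these means do not show how many shared calls come from the shared controls. The log2 fold changes of the 2 comparisons had a covariance of 0.4623, against 0.0497 simulated, a difference of 0.4125, and the same sign in 84.3% of features, against 66.7% simulated. The simulated spread was the same in the 3 groups, while the WT libraries correlated least (0.9354, against 0.9718 in KO and 0.9691 in dPWWP). The simulated covariance may thus be too low. The controls could not be split into parts of 2 libraries, so part of the excess may come from the shared controls. Shared calls numbered 94 higher and 110 lower without KO replicate 1, 41 and 19 without KO replicate 2, 54 and 20 without dPWWP replicate 1, and 86 and 65 without dPWWP replicate 2.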

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

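Of the tests below, those of scaling, intronic transcripts, shared covariance, the numbers of genes detected in KO and dPWWP, and failed estimates were chosen after the result was seen.

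Only genes found by the naming rule or its protein-coding repeat in KO against dPWWP were looked at here. For 15 of these the fitted effects of KO and dPWWP against WT had opposite signs and their difference passed limma (adjusted p between 0.000102 and 0.0425). For 4 of them, CHCHD2, ZBED10P, HMGA1P3 and MOK, both effects against WT passed. For the other 11 only 1 of the 2 effects passed, and the one that did not was as small as -0.02 for GPAT2 in dPWWP (adjusted p = 0.962), -0.06 for TDRD1 in dPWWP (0.858), 0.12 for NNAT in KO (0.568) and 0.21 for CEBPZOS in KO (0.62), so opposite effects are not shown for these genes. The KO minus dPWWP difference in log2(FPKM + 1) was 5.53 for CHCHD2, a fitted value and no bound since dPWWP is listed at 0, 3.32 for CEBPZOS, 2.52 for GNAS-AS1, 2.44 for ZBED10P, 2.44 for LRRC61, 2.40 for GPAT2, 2.18 for VAV1, 1.96 for MOK, 1.95 for NNAT, 1.93 for TDRD1 and 1.90 for C5orf63. It was -2.35 for HMGA1P3, -1.95 for GAMT, -1.78 for RASA3 and -1.56 for CPS1. For 2 gene lists the medians against WT also had opposite signs and the camera test of the difference passed, germline genes (adjusted p = 2.64e-09) and replication-dependent histones (adjusted p = 6.79e-15), though neither passed with an estimated correlation (adjusted p = 0.718 and 0.964). The germline median in dPWWP was only -0.08 (camera adjusted p = 0.709) and turned to 0.14 under TPM, where the median of all features moved up by 0.2569. The histone median in KO was only 0.07 (camera adjusted p = 0.542), so opposite effects are not shown for these 2 lists either.

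A broad pattern was that both edited lines stood apart from WT in many features, of which 912 were higher and 1207 lower in both, including intronic transcripts and mitochondrial RNA. Lower detection in WT as the whole cause would confine calls to low genes, but 19.8% of the 5311 genes with a mean FPKM of 20 or more were called in KO against WT. Part of the calls may still come from it. In KO against WT, 245 called features were listed at 0 in both libraries of 1 group. The remaining calls were 1251 higher and 1794 lower, against 1474 and 1816 in all. In dPWWP against WT, 230 were so listed, which left 1163 higher and 1528 lower, against 1369 and 1552. Scaling as the whole cause is opposed by the 1315 calls made under TPM, 40% of the number as deposited, of which 1214 were also called in the same direction as deposited. Unspliced RNA stays open as a cause. The median of 26 intronic transcripts was -1.23 in KO and -1.17 in dPWWP against WT, at percentile 0 of random sets in both. This restates the pattern, and any cause of lower intronic transcripts would give it, so it cannot decide. For protein-coding genes the correlation of genomic span with the KO fold change, across genes that are not independent replicates, was rho = -0.272 (-0.2448 in dPWWP), between the bounds set for and against. Loss of normal DNMT3B stays open too. The excess covariance of 0.4125 cannot be told apart from a preparation difference of the WT libraries, which served both comparisons. Nor can it be told apart from any other difference that both edited lines share against WT. A library batch was not tested, since the labels give none.

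In KO against dPWWP, 24 germline genes had a median of 0.52 and passed camera, but neither with an estimated correlation (adjusted p = 0.718) nor by fry (0.176), and 1 member, TDRD1, passed limma over all genes, a call lost without each of the 4 KO and dPWWP libraries in turn. Germ cells rich in DDX4, DAZL, SYCP3, SYCP1, BRDT, LDHC and BOLL are opposed in the KO cultures by low values of these 7 transcripts. The median of the 7 was 0.335 FPKM in KO and 0.337 in dPWWP, and none of the 7 exceeded 2.21 in a KO library. DAZL and LDHC are also on the germline list. Germ cells that lack these transcripts were not tested for. More genes detected in KO is opposed by mean numbers above 0 of 27876 and 27754.5, a difference of 0.438%, though this only stands in for depth, which is unknown. Whether the knockout and the PWWP deletion act differently on these genes was not tested apart from a difference between the particular edited lines, and both stay open.

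CHCHD2 was listed at 0 in both dPWWP libraries and at 26.1 to 51.9 FPKM in the other 4, and the deposited group table lists it at 0 in dPWWP as well. Reads moved to its pseudogenes are opposed by the pseudogenes' summed FPKM, which was only 0.109 higher in dPWWP than in WT. A failed estimate stays open. CHCHD2 was the only protein-coding gene, 1 in all, listed at 0 in both libraries of a group and at 20 FPKM or more in the other 4. But 15 other features are at 0 in all 6 library files while the group table lists them above 0 in at least 1 group. SEM1 was the only abundant one (307.6 in WT), and the others were at most 2.79 in any group. They differ from CHCHD2, for which the library files and the group table both list 0 in dPWWP. Loss of CHCHD2 expression in the dPWWP line was not tested otherwise and stays open as well.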

How the results depend on the processing

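Restricting the test to protein-coding genes and leaving out features that differ between the deposited tables were chosen after the data were seen; the other alternatives were planned, and the group table, which holds no libraries, could give no value. Counts are given as higher and lower, for KO vs WT, dPWWP vs WT, KO vs dPWWP and shared calls where they moved by over 1.5 times. Without a filter they were 777 and 759, 508 and 478, 14 and 11, and 268 and 389, with more features tested and 5 lists past camera in KO vs dPWWP. Under TPM, KO vs WT gave 921 and 394, dPWWP vs WT 325 lower and shared calls 234 lower, and without mitochondrially encoded and small RNA genes in the total the lower calls were 1133, 892 and 649. TPM divides by the FPKM sum, which was largest in WT replicate 2 (709718, with 25.74% in small RNA genes). This moved the median of all features up by 0.2027 in KO vs WT and 0.2569 in dPWWP vs WT. Other causes were not tested. Fits on 2 groups, with fewer samples, gave 687 and 877, 341 and 400, and 210 and 325 shared. In KO vs dPWWP the same kind of fit gave 35 and 23, against 37 and 21, so fewer samples alone need not explain the fall. The WT libraries correlated least (0.9354, against 0.9718 in KO and 0.9691 in dPWWP), and the main fit shared its spread over the groups. Adjusted p-values against WT may thus be too small. Protein-coding genes alone gave 60 and 42 in KO vs dPWWP, and an adjusted p under 0.10 gave 1684 and 1992 shared. With the replicate number as a block the counts were 879 and 1112, 721 and 815, 20 and 11, and 460 and 640, and ribosomal proteins in dPWWP vs WT had an adjusted p of 0.0714; the numbers do not show a pairing, since deviations of same-numbered libraries correlated at 0.1002 (WT and KO), -0.0471 (WT and dPWWP) and -0.0176 (KO and dPWWP).

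Lists past camera in KO vs WT numbered 2 at a minimum of 5 FPKM and 7 under quantile normalization. With an estimated correlation 0, 0 and 0 lists passed in the 3 comparisons, and by fry 0 in dPWWP vs WT and 0 in KO vs dPWWP, where limma gave 6123 and 1477 features at an unadjusted p under 0.05. Ribosomal proteins reversed under quantile normalization (camera adjusted p = 0.00081 in dPWWP vs WT and 0.904 in KO vs dPWWP), and the cause was not tested. DNMT3B under TPM was -0.86 in KO vs WT and -0.17 in dPWWP vs WT. The median of all features moved the same way, by 0.2027 and 0.2569, since the FPKM sum was largest in WT replicate 2.

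With each library left out in turn, and a lone library assumed to vary like the other groups, counts ranged from 42 to 1634 higher and 21 to 1489 lower in KO vs WT, 57 to 1537 and 23 to 1322 in dPWWP vs WT, 1 to 41 and 0 to 28 in KO vs dPWWP (1477 at an unadjusted p under 0.05 with all libraries), and 41 to 1083 and 19 to 957 shared. Lists past camera ranged from 3 to 6 in KO vs WT, 3 to 4 in dPWWP vs WT and 2 to 4 in KO vs dPWWP. DNMT3B ranged from -1.21 to -0.95 in KO vs WT. Over the alternatives, named genes kept their direction and side of the threshold in 1205 of the results in KO vs WT, 944 in dPWWP vs WT and 663 in KO vs dPWWP, lost the call in 144, 161 and 138, gained one in 21 (dPWWP vs WT) and 12 (KO vs dPWWP), and 0 reversed. Unknown depth leaves low values without a counting error.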

Other observations

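The chromosome medians below were planned before the data were examined, and no test in this part was chosen after the result was seen. In the mesenchyme and fibroblast list, 3 of 26 genes rose and 6 fell in KO against WT by limma. COL1A1 fell by 2.02, CCN1 by 1.40 and COL6A2 by 1.26, while the intermediate filament gene VIM rose by 0.83; in dPWWP 3 rose and 4 fell. Interferon response genes did not move together, with 3 of 35 rising and 1 falling in KO and 5 rising and 2 falling in dPWWP. IFITM3 rose by 1.19 in KO and 1.28 in dPWWP, and BST2 changed by -1.63 and -1.23. In the list of the unfolded protein and integrated stress responses, 1 of 36 genes rose and 5 fell in KO, and 3 rose and 8 fell in dPWWP, where PSAT1, an enzyme of serine synthesis, changed by -1.26 and the cystine transporter SLC7A11 by -0.91. Among 30 p53 targets 3 rose in KO and 1 rose and 1 fell in dPWWP, with BAX at 1.52 in KO. Camera gave an adjusted p of 0.72, 0.909, 0.404 and 0.0535 in KO and of 0.709, 0.709, 0.21 and 0.21 in dPWWP for these 4 lists, in the order given.

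Markers of other cell types were mostly below the expression minimum. Of 28 endoderm genes 5 were kept, of 34 primitive streak and mesoderm genes 8, of 32 neural and ectoderm genes 10 and of 32 trophoblast genes 5. In KO, 0 endoderm genes passed (limma, with 6387 features at an unadjusted p under 0.05), TNNT2, a troponin gene of heart muscle, fell by 1.12, the neuronal tubulin gene TUBB3 rose by 1.04 and FABP7, a radial glia gene, fell by 1.55, and 1 trophoblast gene rose. In dPWWP, 2 of the 5 endoderm genes rose and 0 fell, among them CLDN6, a tight junction gene, by 0.59; all 5 had a positive log2 fold change, with a median of 0.5898, and the list did not pass camera (adjusted p = 0.124). Also in dPWWP, 2 mesoderm genes fell, 1 neural gene, TUBB3, rose by 1.01 and 1 fell, and 0 trophoblast genes passed (limma, with 6123 features at an unadjusted p under 0.05). Of 47 cell cycle genes, 2 rose and 2 fell in KO, with PCNA at 0.50 and MKI67 at -1.18, and 3 rose and 6 fell in dPWWP. Of 461 ZNF genes, 20 rose and 46 fell in KO, 26 rose and 44 fell in dPWWP, and 1 was higher and 1 lower in KO than in dPWWP. Of 26 glycolysis genes 2 rose and 1 fell in each edited line, and of 30 genes of Polycomb complexes 2 rose and 3 fell in KO and 1 rose and 2 fell in dPWWP. In KO, 5 of 49 histone genes rose and 2 fell, with H3C1 at 1.43 and H2AC14 at -1.62, and the 77 ribosomal protein genes had a camera adjusted p of 0.56. These splits depended on scaling. Under TPM, the cell cycle genes that rose and fell were 1 and 1 in KO and 8 and 0 in dPWWP, the ZNF genes 7 and 3 in KO and 13 and 4 in dPWWP, the mesenchyme genes 3 and 2 in KO and 4 and 3 in dPWWP, and the stress response genes 1 and 0 in KO and 1 and 1 in dPWWP. The p53 targets that rose and fell under TPM were 4 and 0 in each edited line, the glycolysis and the Polycomb genes 1 and 0 in KO and 0 and 0 in dPWWP, the interferon response genes 4 and 1 in KO and 5 and 1 in dPWWP, and the histone genes 8 and 4 in KO. The 4 kept members of X-linked cancer-testis families included 0 called genes in each comparison. These lists did not pass camera in either comparison against WT, apart from histones and ribosomal proteins in dPWWP.

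The highest chromosome median of the log2 fold change was on chromosome 20, where 398 features had a median of 0.0942 in dPWWP against WT (percentile 99.5 of 10000 random sets of like expression) and 0.0661 in KO against WT (percentile 96.62). Chromosome 21 went the other way, with a median of -0.08 in KO (percentile 4.92) and -0.0808 in dPWWP (percentile 2.3). At 20q11.21, a band that is often gained in cultured human embryonic stem cells, 16 kept genes had a median of 0.2925 in KO (percentile 98.21) and 0.1024 in dPWWP (percentile 76.94), with 4 genes rising and 1, DNMT3B, falling in KO; the list did not pass camera (adjusted p = 0.288 and 0.675). Under TPM 2 genes of this band rose and 0 fell in KO, 0 passed in dPWWP (1 rose as deposited), and the median was 0.512 in KO and 0.3816 in dPWWP, and relative to the median of all genes it was 0.3016 and 0.1109, against 0.2848 and 0.0886 as deposited. No copy number was measured. Chromosome 12 had a median of 0.0221 in KO against dPWWP (percentile 100), against -0.0222 in random sets. Chromosome 19 had one of -0.0487 (percentile 0.54), against -0.0268. In the same comparison chromosome 10 lay at percentile 97.27 and X at 1.91, and chromosome 19 lay at 98.47 in dPWWP against WT. The percentiles were not adjusted over regions and comparisons, and genes of a region are not independent.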
